A study of Mus musculus with 20 samples.

How the data were processed

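RNA was sequenced from dissected corpus callosum and optic nerve of Zdhhc9 knockout and wild-type mice, in 20 libraries made with a stranded mRNA kit per the extract protocol in the labels. Brains and nerves were frozen, and the callosum was dissected from cryostat sections of the brain. The deposited table holds, per the labels and its values, the expected_counts unit, that is an estimated count of reads per gene for each library, which the authors did not scale to a common total. It has 46517 genes, 46005 of them with a symbol in the matching annotation and 118 symbols that occur more than once; 22291 genes are at 0 in every library, and 30.14% of the values above 0 are whole numbers within a tolerance of 1e-06. The genome build is mm10 per the submitters' processing notes. The quantifier's version, the transcript annotation, the way transcripts were summed to genes, the sequencer and the read length are not given in the sources used here. Column totals ranged from 15401130 to 26095622, and 0 pairs of libraries were identical. Positions of genes come from an annotation matched to the table's gene identifiers.

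Libraries were grouped by tissue and genotype as the labels give them, with 6 knockout and 5 wild-type callosum libraries and 5 knockout and 4 wild-type optic nerve libraries, and each was treated as a separate sample within its tissue. Estimated counts were rounded, genes were filtered with filterByExpr (minimum count 10, minimum total 15), and libraries were scaled with TMM factors. Each tissue was fitted apart with the edgeR quasi-likelihood test; a fit of all 20 libraries in 4 groups gave the difference of the knockout effect between tissues and the difference between tissues. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and in the tissue comparison also needed an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels named as CPM beside a fold change use TMM factors of that comparison, and levels of Zdhhc9 by library are not so scaled. The biological coefficient of variation was 23.7% in corpus callosum and 20.2% in optic nerve.

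Gene lists for the oligodendrocyte lineage, myelin, lipid synthesis, palmitoylation, other glia, neurons, immune and stress responses, and cell types that a dissection can carry along were written with the comparisons, tests and most alternatives before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Several lists share genes, such as Hapln2 in the myelin, mature oligodendrocyte and node lists, and Gfap in both astrocyte lists. Mean list levels (log2 CPM with a prior count of 2) were compared by exact two-sided permutation of the genotype over all 462 groupings in corpus callosum and all 126 in optic nerve, and over 210 within the number formats; this comparison was added after the data were seen. The covariate test used the mean level of the neuron markers and permuted the genotype.

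Genes were named by a rule. It took Zdhhc9 and, for each genotype comparison, the 10 largest rises and 10 largest falls among genes that passed with a mean log2 CPM of at least 1, filled to 5 in each direction with the smallest p, given as values. For the difference between tissues in the effect it took up to 10 genes that passed or else the 5 smallest p, and for the tissue comparison the 10 largest differences in each direction with a mean log2 CPM of at least 5. For each list described it took up to 4 members with the smallest p, and it always took Mbp, Mog, Mag, Mobp, Cnp, Myrf, Pdgfra, Gpr17, Gfap and Aif1. Predicted genes without a name, pseudogenes and genes of the sex chromosomes used for sexing were skipped. Some genes that this rule selects are not reported here.

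Every comparison was checked on 100 groupings of the libraries, the real grouping and 99 others. Alternatives were other scaling factors (DESeq2 size factors, upper quartile), no filter or a stricter filter of 1 CPM, DESeq2, limma-voom with sample quality weights, counts not rounded, a joint fit, 1 surrogate variable, marker levels or number format as covariates, subsets by number format, a replicate block and leaving out each library in turn. The pipeline was tested on simulated counts of the same size and spread per gene, with 200 changed genes and the cholesterol synthesis list shifted by -0.4. In the callosum design edgeR recovered 20% of the genes changed by a log2 fold change of 0.5, 72% of those changed by 1 and 94% of those changed by 1.5, and 4.64% of its calls were unchanged genes; in the optic nerve design it recovered 32%, 72% and 76%, with 4.08% unchanged. DESeq2 had 15.9% and 17.1% unchanged genes among its calls there, and limma-voom with sample quality weights 4% and 4.7%. Many changes below a log2 fold change of 1 would thus be missed at this number of replicates. The simulated genes varied independently, without the variation that genes of a real library share. These error shares therefore need not hold for the real libraries. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.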

Results

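RNA sequencing measured messenger RNA in 20 mouse libraries of white matter, from Zdhhc9 knockout and wild-type mice. The corpus callosum, the fibre tract that joins the cerebral hemispheres, gave 6 knockout and 5 wild-type libraries. The optic nerve, the tract that leaves the retina, gave 5 knockout and 4 wild-type libraries. The sample labels say knockout, while the series description calls the same mice a knockdown. Zdhhc9 codes for an enzyme that attaches palmitate to proteins, and the title of the series ties it to X-linked intellectual disability and to the maturation of oligodendrocytes, the cells that make myelin. The comparisons ask which transcripts differ with the genotype in each tract and whether the effect differs between the tracts. Total estimated counts per library ranged from 17333746 to 25028817 in knockout and from 15401130 to 25375187 in wild-type corpus callosum. In optic nerve they ranged from 18837907 to 25866142 in knockout and from 22299837 to 26095622 in wild type. Libraries are named as in the labels, with the genotype, the tissue (CCg or ON) and the number of the sample. The p-values below measure the spread between these libraries, which the labels give as separate samples.

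Zdhhc9 (ENSMUSG00000036985.11, mm10 chromosome X, 48171969 to 48208878) was lower in each of the 11 knockout libraries than in any wild-type library of the same tissue. In corpus callosum its level was 43.1, 51.2, 52.7, 56.8, 44.8 and 48.9 CPM, which is counts scaled to the total of the library, in KO_CCg_27, KO_CCg_29, KO_CCg_693451, KO_CCg_693452, KO_CCg_717651 and KO_CCg_719856. It was 182, 186, 194, 205 and 158 CPM in WT_CCg_28, WT_CCg_30, WT_CCg_685232, WT_CCg_717652 and WT_CCg_7198587. In optic nerve it was 49.6, 34.5, 48.1, 34.3 and 40.0 CPM in KO_ON_48038A7, KO_ON_48118A4, KO_ON_693452, KO_ON_717651 and KO_ON_719856. It was 135, 138, 115 and 142 CPM in WT_ON_700858, WT_ON_701297, WT_ON_717652 and WT_ON_719857. Zdhhc9 fell by 1.95 on the log2 scale in corpus callosum, to 25.9% of the wild-type level (SE 0.10, adjusted p = 1.8e-06, 6 against 5 libraries). In optic nerve it fell by 1.70, to 30.8% (SE 0.13, adjusted p = 5.4e-04, 5 against 4 libraries). A transcript level of this size remained in the knockout libraries, and the labels do not say which part of the gene was changed. The difference between the tissues in this effect was -0.26 (SE 0.17, adjusted p = 0.764).

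In corpus callosum, Svep1 and Kit rose in the knockout, and Slco3a1, Apln and Slc45a3 fell along with Zdhhc9. Svep1 (ENSMUSG00000028369.14, chromosome 4, 58042442 to 58206859), which codes for a large extracellular matrix protein, reached 8.9 ± 1.1 CPM (SD, n = 6) against 2.88 ± 0.34 CPM (SD, n = 5), a log2 fold change of 1.63 (SE 0.13, adjusted p = 2.3e-04). Kit (ENSMUSG00000005672.11, chromosome 5, 75574916 to 75656722), the receptor tyrosine kinase for stem cell factor, reached 48.5 ± 8.01 against 25.1 ± 2.68 CPM, a log2 fold change of 0.95 (SE 0.12, adjusted p = 0.0272). Slco3a1 (ENSMUSG00000025790.13, chromosome 7, 74275419 to 74554780), an organic anion transporter, fell from 101 ± 16 to 57.6 ± 4.72 CPM, a log2 fold change of -0.81 (SE 0.11, adjusted p = 0.0362). Apln (ENSMUSG00000037010.7, chromosome X, 48025146 to 48034853), which codes for the peptide ligand apelin and lies on the same chromosome as Zdhhc9, fell from 43 ± 6.71 to 24.1 ± 2.9 CPM, a log2 fold change of -0.83 (SE 0.12, adjusted p = 0.044). Slc45a3 (ENSMUSG00000026435.14, chromosome 1, 131962967 to 131982969), a membrane transporter, fell from 10.48 ± 1.34 to 5.73 ± 0.759 CPM, a log2 fold change of -0.87 (SE 0.13, adjusted p = 0.0486). For each of these 5 genes, 6 of 6 knockout libraries lay beyond every wild-type library.

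**Figure D1:**
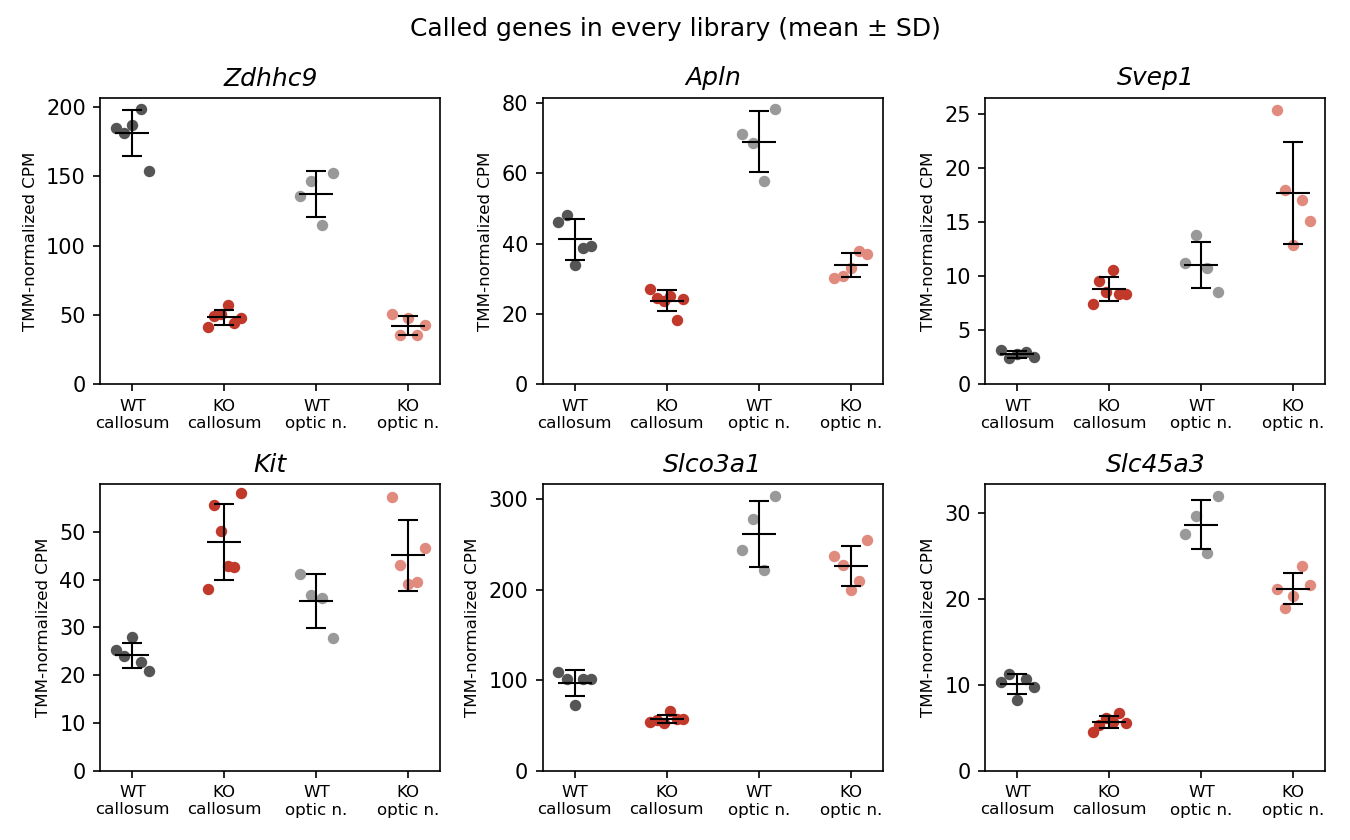
Level of the 6 genes called in corpus callosum, in CPM scaled with factors from all 20 libraries, with 1 point per library and the mean and SD of each of the 4 groups. The 6 knockout callosum libraries lie beyond the 5 wild-type ones for every gene drawn, and Apln is lower in the 5 knockout optic nerve libraries than in the 4 wild-type ones.

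These were 6 genes of 15519 tested by edgeR (2 higher, 4 lower), while 1816 had an unadjusted p under 0.05 where 776 would be expected by chance. The calls of Kit, Slco3a1, Apln and Slc45a3 lie near the threshold. With single libraries left out in turn, the count of genes changed in corpus callosum was 41 without WT_CCg_685232 and 3 without KO_CCg_27 or KO_CCg_29. It was 2 without any of KO_CCg_693451, KO_CCg_719856, WT_CCg_28, WT_CCg_30, WT_CCg_717652 and WT_CCg_7198587. For Kit in corpus callosum, the adjusted p was 0.109 without KO_CCg_693451 and 0.0729 without KO_CCg_719856. It was 0.0857, 0.116, 0.143 and 0.108 without WT_CCg_28, WT_CCg_30, WT_CCg_717652 and WT_CCg_7198587. Slco3a1 in corpus callosum stayed called only without KO_CCg_693452 or WT_CCg_685232, and its adjusted p ran from 0.0648 to 0.151 without any other library. For Apln in corpus callosum only leaving out WT_CCg_685232 kept the call (0.0568 to 0.162 without any other). For Slc45a3 in corpus callosum only leaving out KO_CCg_717651 or WT_CCg_685232 kept it (0.0863 to 0.241 without any other). DESeq2 called 167 genes (49 higher, 118 lower), and limma-voom with sample quality weights called 2786 (1474 higher, 1312 lower). Both sets held all 6.

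Sample numbers in corpus callosum came in 2 formats, with 2 digits (2 knockout, 2 wild type) or with 6 or 7 digits (4 knockout, 3 wild type), and expression differed widely between the formats. Within the 2-digit and the longer format, the log2 fold changes were 1.53 and 1.63 for Svep1 and 0.87 and 0.98 for Kit. They were -0.98 and -0.67 for Slco3a1, -0.91 and -0.75 for Apln, -1.15 and -0.69 for Slc45a3, and -2.05 and -1.89 for Zdhhc9. With the format as a covariate edgeR called 10 genes (2 higher, 8 lower), all 6 among them. In the longer format alone it called 2, Zdhhc9 and Svep1. Other covariates ended some of the calls. With the mean level of the neuron markers, Slco3a1, Apln and Slc45a3 had adjusted p of 0.1001, 0.121 and 0.146, while Svep1 and Kit stayed called. With that level and the format together, Slco3a1 and Slc45a3 lost their calls (0.155 and 0.209). Slc45a3 lost it with the fibroblast level (0.0778) and with 1 surrogate variable (0.0629) too. Of all 26 alternatives, left-out libraries among them, 18 ended the call of Slc45a3. For Slco3a1 and Apln 13 each did so, and for Kit 8. With cortical and striatal marker levels only Zdhhc9 and Svep1 passed, and Kit had 0.107 and Slco3a1, Apln and Slc45a3 0.986. Fold changes kept their direction in each of these fits. Over all alternatives they ran from -0.90 to -0.61 for Slco3a1 and from -0.91 to -0.65 for Apln. They ran from -0.94 to -0.67 for Slc45a3 and from 0.89 to 1.10 for Kit. Genes named by the rule that did not pass were Syt2, a calcium sensor of synaptic vesicles, at 1.24 (SE 0.24), Flrt3, a cell adhesion protein, at 0.66 (SE 0.13), and Fbxw15 at 1.14 (SE 0.22), each with an adjusted p of 0.139. The mechanically gated channel gene Piezo2 was at -1.23 (SE 0.20, adjusted p = 0.0792).

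Myelin transcripts were lower in knockout corpus callosum as a group by camera, though not by exact permutation after adjustment (adjusted p = 0.105). No member passed the test over all genes. Of the 28 myelin protein genes 27 had a negative log2 fold change (median -0.39), and the list fell by camera (adjusted p = 7.2e-15; adjusted p = 0.225 with an estimated correlation). Adjusted over the list alone, 10 members were lower. They include the perinodal matrix gene Hapln2 at -1.14 (SE 0.23), the gap junction gene Gjb1 at -0.63 (SE 0.18), and Mobp, which codes for a basic protein of compact myelin, at -0.76 (SE 0.22). Mobp stood at 6746 ± 2007 CPM (SD, n = 6) against 11403 ± 2605 CPM (SD, n = 5). Mbp, which codes for a main protein of compact myelin, was at -0.62 (SE 0.20, adjusted p = 0.34 over all genes). Mog, a protein of the outer myelin surface, was at -0.49 (SE 0.17), the adhesion protein gene Mag at -0.42 (SE 0.18) and the enzyme gene Cnp at -0.35 (SE 0.16). Within the 2-digit and the longer format, the fold changes were -0.73 and -0.57 for Mbp and -0.82 and -0.71 for Mobp. With the neuron marker level as a covariate they shrank to -0.35 for Mbp, -0.42 for Mobp, -0.23 for Mog, -0.23 for Mag and -0.17 for Cnp, and the list median to -0.16. With the number format added, they were -0.27, -0.39, -0.19, -0.10 and -0.071, and the list median was -0.11 (camera adjusted p = 1.2e-05). With cortical and striatal levels instead, Mog was at -0.18 and the list median at -0.14. The share of all counts held by this list was 5.93 ± 1.38% in knockout and 8.47 ± 1.48% in wild type (exact permutation p = 0.0238, two-sided, adjusted p = 0.0714 over 6 library measures).

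Along the oligodendrocyte lineage, the lists of mature and newly formed cells fell by camera, and the mature list had the lowest median. By exact permutation of the mean level neither passed after adjustment (adjusted p = 0.0628 for mature and 0.201 for newly formed cells). No member of the lineage lists passed the test over all genes. Of 22 mature oligodendrocyte markers 20 were negative (median -0.53, camera adjusted p = 2.8e-16; adjusted p = 0.139 with an estimated correlation). Of these, 12 were lower when adjusted over the list alone. They include the membrane protein gene Pmp22 at -0.95 (SE 0.17), Hapln2, the iron carrier gene Trf at -0.74 (SE 0.16) and the protease inhibitor gene Serpinb1a at -0.73 (SE 0.17). Markers of newly formed oligodendrocytes fell as well (15 of 16 negative, median -0.29, camera adjusted p = 2.4e-05; adjusted p = 0.377 with an estimated correlation). Enpp6 at -0.73 (SE 0.20) and Neu4 at -0.53 (SE 0.15) were lower over the list alone. The newly formed cell marker Gpr17 itself was at -0.38 (SE 0.19). The 15 precursor markers had a median of -0.12 and a camera adjusted p of 0.0413, lost with an estimated correlation (adjusted p = 0.380). Pdgfra, the growth factor receptor of precursors, was at -0.26 (SE 0.09), and 0 of 15 passed over the list alone. Lineage transcription factors had a median of -0.18 over 19 genes (camera adjusted p = 0.00298; adjusted p = 0.380 with an estimated correlation). Sox8 was at -0.47 (SE 0.15) and Myrf, which drives myelin gene transcription, at -0.33 (SE 0.18), and 0 of 19 passed over the list alone.

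Lipid synthesis genes were lower in knockout corpus callosum by camera, although no member passed the test over all genes. Of 25 genes of cholesterol synthesis and uptake 24 were negative (median -0.42, camera adjusted p = 2.6e-21; adjusted p = 0.0797 with an estimated correlation). Of these, 19 were lower when adjusted over the list alone. The demethylase gene Cyp51 was at -0.51 (SE 0.09), the sterol sensor Insig1 at -0.51 (SE 0.10) and Sqle, which codes for squalene epoxidase, at -0.49 (SE 0.10). Fatty acid and sphingolipid synthesis genes fell too (25 of 28 negative, median -0.24, camera adjusted p = 6.9e-09; adjusted p = 0.139 with an estimated correlation). Over the list alone 8 were lower. Among these were the desaturase gene Scd1 at -0.71 (SE 0.18), the fatty acid hydroxylase gene Fa2h at -0.60 (SE 0.16) and Ugt8a, whose enzyme makes the myelin lipid galactosylceramide, at -0.67 (SE 0.20).

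Glial and immune markers were also lower by camera, again with no member past the test over all genes. All 17 microglia markers were negative (median -0.35, camera adjusted p = 1.1e-13; adjusted p = 0.0797 with an estimated correlation). Adjusted over the list alone, 14 passed, such as the integrin gene Itgam at -0.39 (SE 0.09) and the complement gene C1qa at -0.46 (SE 0.11). Aif1, a microglial gene named by the rule, was at -0.28 (SE 0.15). Genes of damage-associated microglia fell (median -0.25, 14 of 15 negative, camera adjusted p = 3.9e-04; adjusted p = 0.218 with an estimated correlation). Over the list alone 4 were lower, the integrin gene Itgax at -1.08 (SE 0.30) among them. Antigen presentation genes were negative in 10 of 10 (median -0.55, camera adjusted p = 5.8e-09; adjusted p = 0.0797 with an estimated correlation). Of the 10, 9 passed over the list alone, including the invariant chain gene Cd74 at -1.16 (SE 0.30) and the class I genes H2-D1 at -0.58 (SE 0.15) and H2-K1 at -0.53 (SE 0.15). Interferon-stimulated genes had a median of -0.64 (14 of 15 negative, camera adjusted p = 2.5e-08; adjusted p = 0.218 with an estimated correlation). The mean level of this list did not pass by exact permutation (p = 0.0498, adjusted p = 0.131). Its SD over libraries was 0.51 in wild type and 0.12 in knockout, and 0 knockout libraries lay below every wild-type library. Without WT_CCg_7198587 the median of the interferon list was -0.48. Past the list alone were 4, such as Ifi27 at -0.64 (SE 0.12). Reactive astrocyte genes were negative in 11 of 11 (median -0.45, camera adjusted p = 3.3e-06; adjusted p = 0.139 with an estimated correlation). Over the list alone 4 passed, including the intermediate filament gene Gfap at -0.58 (SE 0.15), 616 ± 104 against 920 ± 177 CPM. General astrocyte markers had a median of -0.14 over 15 genes (camera adjusted p = 0.0425; adjusted p = 0.377 with an estimated correlation), with Gfap lower over the list alone.

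Neuronal transcripts were higher in knockout corpus callosum by camera, though not by exact permutation after adjustment. No member of the lists below passed the test over all genes. All 18 neuron markers were positive (median 0.65, camera adjusted p = 1.9e-08; adjusted p = 0.372 with an estimated correlation). The dendrite protein gene Map2 was at 0.59 (SE 0.22) and the neurofilament gene Nefm at 0.70, and 0 of 18 passed over the list alone. Of 12 markers of striatal projection neurons all were positive and all 12 were higher over the list alone (median 0.85, camera adjusted p = 1.6e-14; adjusted p = 0.139 with an estimated correlation). Among them were the dopamine receptor gene Drd1 at 0.95 (SE 0.24) and the phosphodiesterase gene Pde10a at 0.95 (SE 0.26). Markers of cortical excitatory neurons were positive in 11 of 12 (median 0.60, camera adjusted p = 0.0114; adjusted p = 0.380 with an estimated correlation), with 0 of 12 past the list alone. The share of counts held by the neuron markers was 0.485 ± 0.174% in knockout and 0.310 ± 0.138% in wild type (exact permutation p = 0.104, two-sided, adjusted p = 0.208 over 6 library measures). By exact permutation of the mean list level, neuron markers had p = 0.132 (adjusted p = 0.225) and cortical markers p = 0.392 (adjusted p = 0.513). Striatal markers had an exact permutation p = 0.0238 (adjusted p = 0.0863). Channels and adhesion proteins of the node and paranode, made in part by neurons, had a median of 0.25 over 18 genes (camera adjusted p = 0.0425; adjusted p = 0.377 with an estimated correlation). Over the list alone 2 of 18 passed, both lower, and the oligodendrocyte gene Hapln2 was among them.

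**Figure D2:**
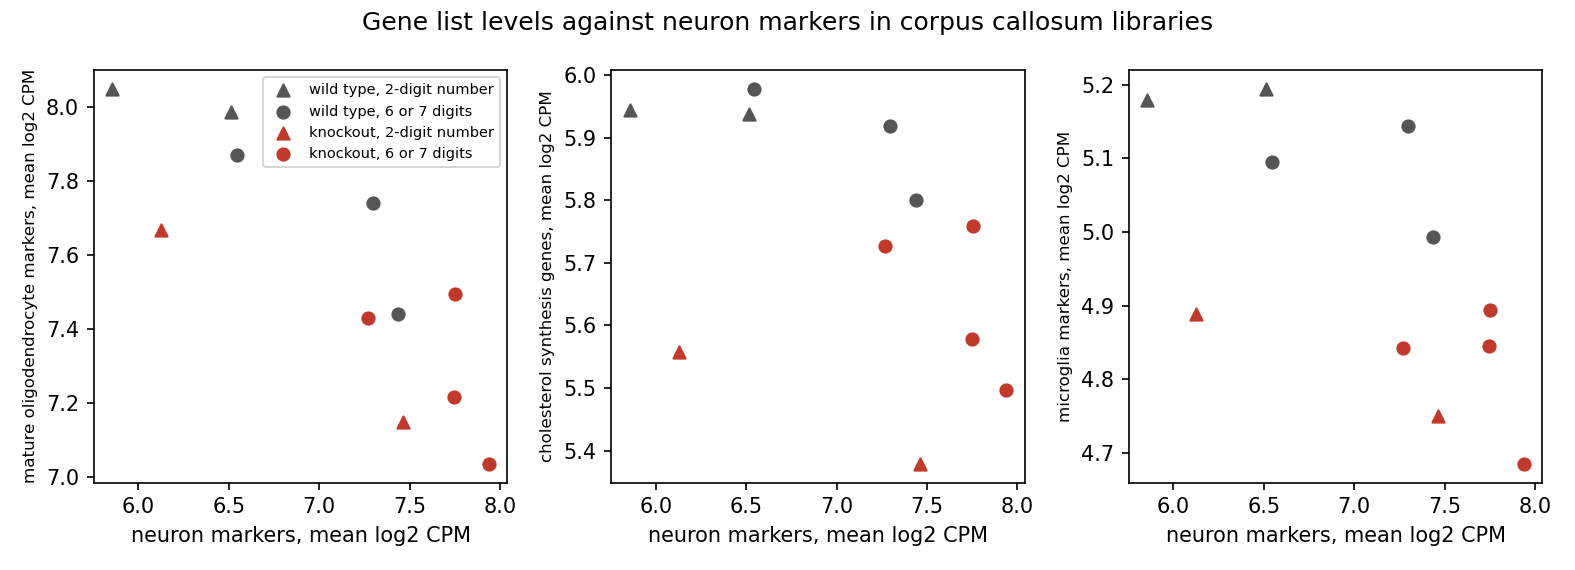
Mean log2 CPM of the mature oligodendrocyte, cholesterol synthesis and microglia lists against that of the neuron markers, with 1 point per corpus callosum library, by genotype and number format. The cholesterol and microglia levels of the 6 knockout libraries lie below those of the 5 wild-type libraries.

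Neuron marker levels moved together with these groups. The first principal component, the axis along which the callosum libraries varied most, held 60.4% of the variance. Its correlation with the neuron marker level was 0.988 in size. Each list's mean level was therefore tested again with the neuron marker level of the library as a covariate. The knockout coefficient was then -0.33 for cholesterol synthesis (SE 0.083), -0.15 for fatty acid and sphingolipid synthesis (SE 0.036), -0.27 for microglia markers (SE 0.050) and -0.60 for antigen presentation (SE 0.134), each with a permutation p adjusted to 0.0303. It was -0.31 for mature oligodendrocyte markers (SE 0.10, adjusted permutation p = 0.0707) and -0.35 for reactive astrocyte genes (SE 0.111, adjusted permutation p = 0.0606). The coefficient was -0.21 for myelin proteins (SE 0.093, adjusted permutation p = 0.182) and -0.40 for interferon-stimulated genes (adjusted permutation p = 0.281). For newly formed oligodendrocyte markers it was -0.073 (SE 0.089, adjusted permutation p = 0.570). In these permutations the coefficient itself was compared. A permuted genotype is less tied to the neuron level than the real one, so the p-values may be too small. For single lists the ratio of the coefficient to its error was not permuted, nor were cortical and striatal levels used in such a permutation. Striatal markers still differed by 0.78 (SE 0.36, permutation p = 0.0455, adjusted 0.182), so the neuron level may not stand for striatal tissue in full. With camera and the same covariate, 7 of the 19 called lists lost their calls, 4 of them with the same sign and 3 with the other. For the 4, the adjusted p was 0.24 for list newly formed oligodendrocyte markers in corpus callosum, 0.68 for list opc markers in corpus callosum, 0.26 for list astrocyte markers in corpus callosum and 0.24 for list axon myelin node genes in corpus callosum. Those that changed sign were lineage transcription factors (median 0.0324, adjusted p = 0.68), cortical neuron markers (-0.154, 0.10) and the neuron markers themselves (-0.0293, 0.62), which the covariate is made of.

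Without a covariate, an exact two-sided permutation of the mean level of each list over the 462 groupings of the 11 libraries passed for 3 of 29 lists. Microglia markers differed by -0.34 and antigen presentation genes by -0.56 (exact p = 0.0022 each, the smallest these groupings can give, adjusted p = 0.0314). Cholesterol synthesis differed by -0.37 (exact p = 0.0043, adjusted p = 0.0418). In these 3 lists 6 of 6 knockout libraries lay below every wild-type library. Mature oligodendrocyte markers differed by -0.52 (exact p = 0.0152, adjusted p = 0.0628) and myelin proteins by -0.44 (exact p = 0.0325, adjusted p = 0.105). Permuted within the number formats, cholesterol synthesis, microglia, antigen presentation and damage-associated microglia passed (adjusted p = 0.0345). Within the 2-digit and the longer format, the differences were -0.50 and -0.30 for cholesterol synthesis, -0.40 and -0.30 for microglia and -0.78 and -0.44 for antigen presentation. In the same order they were -0.64 and -0.43 for mature oligodendrocyte markers, -0.55 and -0.36 for myelin proteins, 0.58 and 0.55 for neuron markers, 1.79 and 0.30 for striatal markers, and -0.10 and 0.58 for cortical markers.

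Other lists in corpus callosum held few or no changed members. Cytosolic ribosomal protein genes fell (81 of 83 negative, median -0.22, camera adjusted p = 1.0e-14; adjusted p = 0.377 with an estimated correlation), with 0 past the list alone. Red blood cell markers had a median of -0.52 over 5 genes (camera adjusted p = 0.0229; adjusted p = 0.380 with an estimated correlation). The remaining lists did not pass. Palmitoylation enzymes other than Zdhhc9 had a median of -0.00 (mean 0.01, adjusted p = 0.874), and immediate early genes 0.12 (0.120). The medians were -0.07 for endothelial and mural markers (0.213), -0.19 for fibroblast markers (0.311), -0.28 for ependymal and choroid markers (0.123) and -0.29 for photoreceptor markers (0.239). They were -0.23 for Schwann cell markers (0.443), -0.16 for stress response genes (0.062), -0.11 for cell cycle genes (0.120) and 0.00 for nuclear genes of oxidative phosphorylation (0.801). In all, camera called 19 of 29 lists (4 higher, 15 lower), against a median of 11 over 99 other groupings of the libraries. Of the 19, 0 passed with an estimated correlation. The fry test, which takes a list by itself, kept 7, those of mature oligodendrocytes, both lipid groups, reactive astrocytes, both microglia groups and antigen presentation. For 5 lists, leaving out 1 library ended the call, and the adjusted p then was as follows. For list erythrocyte markers in corpus callosum it was 0.069 without KO_CCg_29, 0.066 without KO_CCg_717651 and 0.26 without WT_CCg_7198587. For list astrocyte markers in corpus callosum it was 0.052 without KO_CCg_29, 0.053 without KO_CCg_693451 and 0.16 without KO_CCg_717651. There it was also 0.077 without WT_CCg_28, 0.097 without WT_CCg_30, 0.054 without WT_CCg_717652 and 0.066 without WT_CCg_7198587. The value for list opc markers in corpus callosum was 0.056 without KO_CCg_693451, 0.077 without KO_CCg_693452, 0.16 without WT_CCg_28 and 0.088 without WT_CCg_717652. The value for list axon myelin node genes in corpus callosum was 0.067 without KO_CCg_693452, 0.11 without KO_CCg_717651, 0.089 without KO_CCg_719856, 0.16 without WT_CCg_30 and 0.13 without WT_CCg_7198587. That for list cortical neuron markers in corpus callosum was 0.077 without WT_CCg_28. Medians also moved with 1 library left out, to -0.0139 for precursor markers and -0.0547 for lineage transcription factors without WT_CCg_28. They moved to -0.121 for ribosomal proteins and -0.170 for red blood cells without WT_CCg_7198587, and to -0.191 for newly formed oligodendrocytes and -0.0825 for astrocyte markers without WT_CCg_717652. Cortical neuron markers moved to 0.384 without WT_CCg_28.

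In optic nerve, Apln fell along with Zdhhc9, and no other gene passed the test. Apln stood at 32.9 ± 3.31 CPM in knockout (SD, n = 5) and 67 ± 8.37 CPM in wild type (SD, n = 4), a log2 fold change of -1.03 (SE 0.11, adjusted p = 0.00603), with 5 of 5 knockout libraries below every wild-type library. Myelin genes showed small values that did not pass, such as Mog at -0.20 (SE 0.12), Mobp at -0.20 (SE 0.16), Mbp at -0.14 (SE 0.14), Cnp at 0.01 (SE 0.14) and Mag at 0.00 (SE 0.12). Nor did Pdgfra at -0.20 (SE 0.09), Myrf at 0.13 (SE 0.12), Gpr17 at -0.06 (SE 0.16), Gfap at 0.02 (SE 0.14) or Aif1 at 0.12 (SE 0.22) pass, with adjusted p from 0.845 to 0.994 over these 10 genes. The genes nearest to the threshold were Bcat1, an enzyme of branched-chain amino acid breakdown, at -0.95 (SE 0.15, adjusted p = 0.232), 34.9 ± 5.18 against 67.3 ± 15 CPM, and the synaptic scaffold gene Ppfia3 at 0.52 (SE 0.09, adjusted p = 0.357). Kif21b at 0.66 (SE 0.12), Rasal1 at 0.81 (SE 0.15), Adamts1 at 0.59 (SE 0.11), Gabrr2 at 1.22 (SE 0.23), Arid5b at -0.65 (SE 0.12) and the adiponectin receptor gene Adipor2 at -0.53 (SE 0.10) each had an adjusted p of 0.385.

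Of 15556 genes tested in optic nerve, 2 passed (0 higher, 2 lower), and 852 had an unadjusted p under 0.05 where 778 would be expected by chance. In optic nerve DESeq2 called 38 (17 higher, 21 lower) and limma-voom with quality weights called 2. The count of genes changed in optic nerve was 1 without the 2 knockout libraries whose numbers hold a letter, a format absent in wild type, and Apln in optic nerve then had an adjusted p of 0.12 and a log2 fold change of -0.93. Without KO_ON_719856 and WT_ON_701297 together, a set chosen after the data were seen, the count was 1 and the adjusted p of Apln 0.11.

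The 5 genes other than Zdhhc9 that were called in corpus callosum had the same direction in optic nerve, a comparison chosen after the callosum calls were known. Adjusted over these 5 alone, 4 passed. The numbers of 4 nerve libraries also occur in corpus callosum, so the 2 tissues may share animals and need not be independent. The 5 genes were not checked without those nerves. Svep1 was at 0.67 (SE 0.19, adjusted p = 0.0074 over the 5), 17.1 ± 4.40 against 10.7 ± 2.03 CPM, with 4 of 5 knockout libraries above every wild-type library. Kit was at 0.35 (SE 0.13, adjusted p = 0.0314), Slc45a3 at -0.43 (SE 0.10, adjusted p = 0.0020) and Slco3a1 at -0.21 (SE 0.10, unadjusted p = 0.0671). The effect in corpus callosum minus that in optic nerve was 0.94 for Svep1, 0.59 for Kit, -0.61 for Slco3a1, -0.44 for Slc45a3 and 0.19 for Apln, and none of these passed (adjusted p from 0.725 to 0.837).

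Lipid synthesis and mature oligodendrocyte markers were slightly lower in knockout optic nerve by camera, and stimulus-responsive, interferon and neuronal genes were higher. Cholesterol synthesis genes were negative in 22 of 25 (median -0.16, camera adjusted p = 5.0e-07; adjusted p = 0.632 with an estimated correlation). Fatty acid and sphingolipid genes were negative in 22 of 28 (median -0.10, camera adjusted p = 0.00158; adjusted p = 0.679 with an estimated correlation), with 0 past either list alone. Mature oligodendrocyte markers had a median of -0.17 (camera adjusted p = 2.1e-06; adjusted p = 0.547 with an estimated correlation). Over the list alone 6 of 22 were lower, among them the calcium-binding protein gene S100b at -0.46 (SE 0.10), the protease gene Klk6 at -0.41 (SE 0.10) and Pmp22 at -0.31 (SE 0.07). Schwann cell markers had a median of -0.20 over 5 genes (camera adjusted p = 0.0460; adjusted p = 0.547 with an estimated correlation). Immediate early genes were positive in 16 of 16 (median 0.41, camera adjusted p = 5.0e-07; adjusted p = 0.547 with an estimated correlation). Jun was at 0.27 (SE 0.08), and 0 passed over the list alone. Interferon-stimulated genes were positive in 15 of 16 (median 0.41, camera adjusted p = 3.5e-05; adjusted p = 0.632 with an estimated correlation), with Irf7 at 0.71 and Mx1 at 0.82. Antigen presentation genes were positive in 11 of 12 (median 0.26, camera adjusted p = 0.0116; adjusted p = 0.679 with an estimated correlation). Photoreceptor markers were positive in 6 of 6 (median 1.43, camera adjusted p = 0.00154; adjusted p = 0.632 with an estimated correlation). Neuron markers were positive in 15 of 18 (median 0.42, camera adjusted p = 0.00128; adjusted p = 0.721 with an estimated correlation). Tubb3, the neuronal tubulin gene, was the 1 member past the list alone and was lower at -0.48 (SE 0.12). Node genes had a median of 0.14 (camera adjusted p = 0.0385; adjusted p = 0.679 with an estimated correlation).

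The median of cholesterol synthesis genes in optic nerve depended on single libraries, as it was -0.0302 without WT_ON_719857 and -0.258 without WT_ON_700858. Mature oligodendrocyte markers were at -0.0881 and -0.237 without the same libraries, and fatty acid and sphingolipid genes at -0.0390 without WT_ON_719857. Antigen presentation genes fell to 0.139 without KO_ON_719856, and Schwann cell markers were at -0.110 without WT_ON_717652. Neuron markers ran from 0.196 without WT_ON_701297 to 1.08 without WT_ON_717652. Photoreceptor transcripts were high in 1 library, KO_ON_719856. Without it the medians were 0.37 for photoreceptor markers, 0.20 for interferon-stimulated genes, 0.35 for neuron markers and 0.37 for immediate early genes. Leaving out 1 library ended 5 calls. The adjusted p of list antigen presentation in optic nerve was 0.065 without KO_ON_48038A7, 0.12 without KO_ON_719856 and 0.30 without WT_ON_719857. That of list neuron markers in optic nerve was 0.11 without KO_ON_717651 and 0.13 without WT_ON_700858. That of list schwann cell markers in optic nerve was 0.087 without KO_ON_717651 and 0.18 without WT_ON_717652, and that of list fatty acid sphingolipid synthesis in optic nerve was 0.46 without WT_ON_719857. List calls for node genes ended too, with the adjusted p of list axon myelin node genes in optic nerve at 0.07 without KO_ON_693452, 0.44 without KO_ON_717651, 0.34 without WT_ON_700858 and 0.055 without WT_ON_701297. Their median was -0.00431 without KO_ON_717651. The share of counts held by neuron markers was 0.0473 ± 0.0111% in knockout and 0.0428 ± 0.0141% in wild type optic nerve (exact permutation p = 0.627, two-sided), and the myelin list held 8.42 ± 1.26% and 9.34 ± 0.729% (exact permutation p = 0.270).

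Myelin proteins did not pass in optic nerve (12 positive and 16 negative of 28, median -0.05, adjusted p = 0.0981). Newly formed oligodendrocyte markers had a median of 0.05 (adjusted p = 0.143) with 2 higher over the list alone, Cemip2 at 0.32 (SE 0.09) and Kif19a at 0.45 (SE 0.13). The other lists not called had medians of 0.07 for precursor markers (adjusted p = 0.999), -0.04 for palmitoylation (0.276), -0.02 for astrocytes (0.888), and 0.19 for reactive astrocytes (0.0897). They were 0.24 for damage-associated microglia (0.0584), 0.10 for cortical neurons (0.350), 0.16 for striatal neurons (0.302), and -0.01 for endothelial cells (0.302). Medians were 0.09 for fibroblasts (0.888), 0.16 for ependymal cells (0.143), 0.39 for red blood cells (0.114), -0.07 for the cell cycle (0.676), -0.02 for ribosomal proteins (0.101) and -0.01 for oxidative phosphorylation (0.676). Median, mean and test differed in sign for lineage transcription factors (median -0.02, mean 0.01, tested up, 0.897), microglia markers (median 0.01, mean -0.02, tested down, 0.302) and stress response genes (median -0.03, mean 0.04, tested down, 0.742). In all, camera called 10 of 29 lists (6 higher, 4 lower), against a median of 11 over 99 other groupings of the libraries. Of the 10, 0 passed with an estimated correlation, by fry or by exact permutation, where the smallest adjusted p was 0.460.

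**Figure D3:**
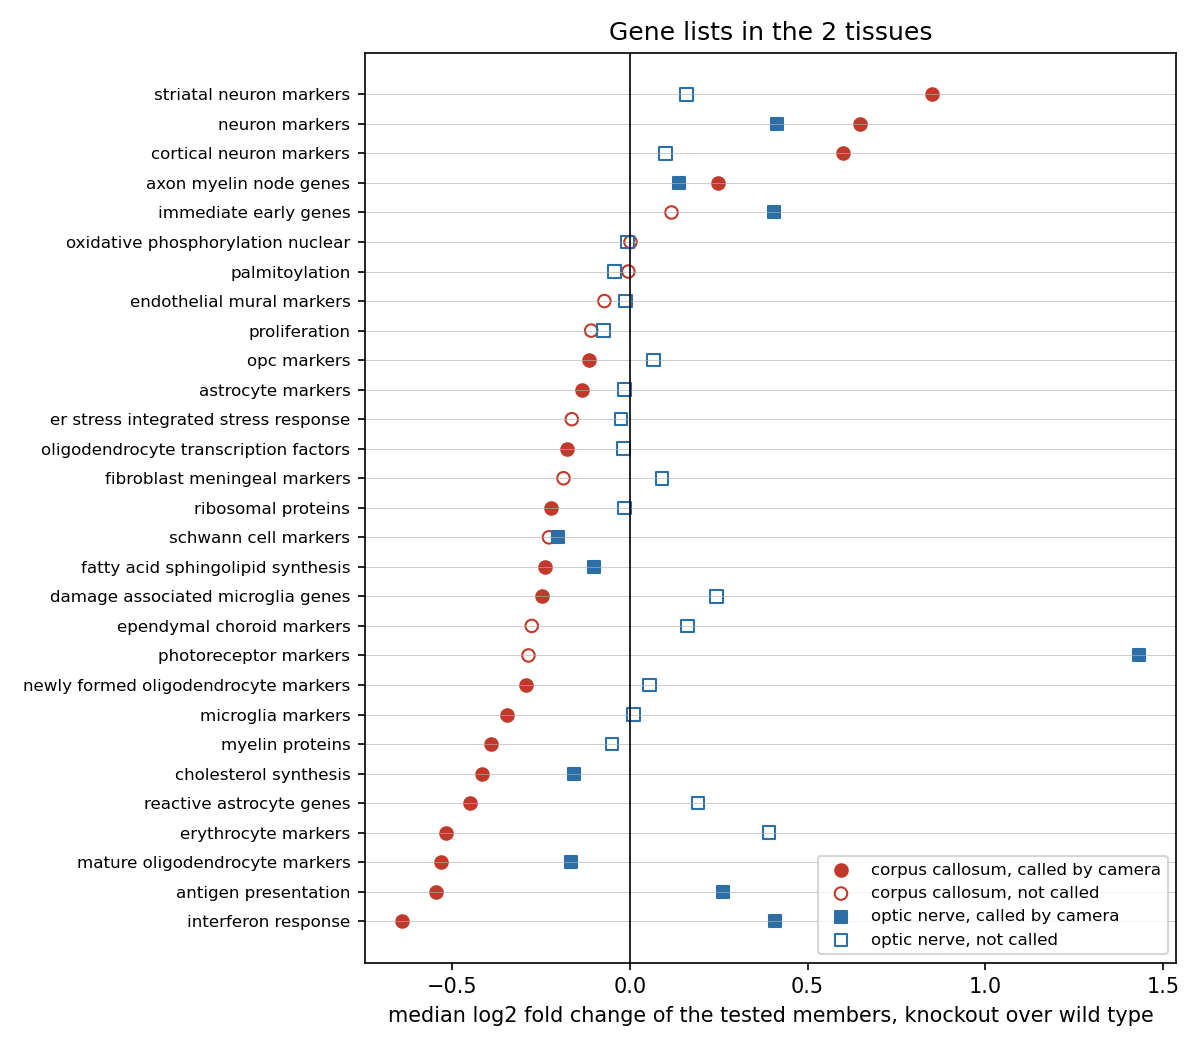
Median log2 fold change of the tested members of each of 29 gene lists, knockout over wild type, in corpus callosum (circles) and optic nerve (squares), filled where camera called the list. Myelin, mature oligodendrocyte and cholesterol lists lie at -0.39, -0.53 and -0.42 in corpus callosum and at -0.05, -0.17 and -0.16 in optic nerve.

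The knockout effect differed between the tissues for gene lists by camera, though for no gene in edgeR. The difference is the effect in corpus callosum minus the effect in optic nerve. Interferon-stimulated genes had the lowest median (-1.07, 16 of 16 negative, camera adjusted p = 4.6e-13; adjusted p = 0.234 with an estimated correlation). Of the 16, 12 passed over the list alone, among them Oasl2 at -1.17 (SE 0.34) and Bst2, which tethers budding virus particles, at -1.27 (SE 0.38). Antigen presentation genes differed too (median -0.86, camera adjusted p = 5.1e-10; adjusted p = 0.234 with an estimated correlation). Of the 12, 8 passed over the list alone, such as the immunoproteasome gene Psmb9 at -1.09 (SE 0.32). Myelin proteins were negative in 28 of 28 (median -0.42, camera adjusted p = 7.5e-10; adjusted p = 0.417 with an estimated correlation). Mature oligodendrocyte markers were negative in 21 of 22 (median -0.37, camera adjusted p = 1.2e-07; adjusted p = 0.371 with an estimated correlation), with 0 past either list alone. Cholesterol synthesis differed by a median of -0.21 (camera adjusted p = 6.4e-05; adjusted p = 0.443 with an estimated correlation), with 1 member past the list alone. Striatal neuron markers differed by 0.67 (camera adjusted p = 1.3e-05; adjusted p = 0.371 with an estimated correlation).

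Further lists with a difference were ribosomal proteins (median -0.20), newly formed oligodendrocytes (-0.35), reactive astrocytes (-0.61), microglia (-0.39) and damage-associated microglia (-0.53). So were fatty acid and sphingolipid synthesis (-0.17), photoreceptors (-1.05), lineage transcription factors (-0.16), immediate early genes (-0.27) and red blood cells (-0.85). Camera adjusted p ran from 1.3e-09 to 0.0133 over these 10 lists, and with an estimated correlation their adjusted p ran from 0.371 to 0.443. Leaving out 1 library ended some of these calls. The adjusted p of list erythrocyte markers between tissues was 0.11 without KO_ON_48118A4 or WT_CCg_7198587, 0.057 without WT_ON_700858 and 0.074 without WT_ON_717652. For list immediate early genes between tissues it was 0.09 without KO_ON_693452 and 0.15 without WT_ON_701297. For list fatty acid sphingolipid synthesis between tissues it was 0.057 without WT_ON_700858, and for list oligodendrocyte transcription factors between tissues 0.097 without WT_CCg_28. The medians of these lists moved as well, to -0.493 for red blood cells without WT_CCg_7198587 and to -0.0991 for immediate early genes without WT_ON_701297. Without WT_CCg_28 they moved to -0.102 for fatty acid and sphingolipid synthesis and to -0.0457 for lineage transcription factors. Photoreceptors kept their call, but their median rested in large part on KO_ON_719856 (-0.350 without it). Damage-associated microglia moved to -0.281 without the same library, striatal neurons to 0.341 without WT_ON_717652, ribosomal proteins to -0.123 without KO_CCg_719856 and cholesterol synthesis to -0.141 without KO_CCg_27. Not called were skeletal muscle markers, which had 5 tested members in this fit alone (median 0.76, adjusted p = 0.108), neuron markers (0.23, 0.0947) and 12 others. Of these, palmitoylation (median -0.01, mean 0.01), cortical neurons (median 0.50, mean -0.09), Schwann cells (median -0.05, mean 0.26) and oxidative phosphorylation (median and mean -0.00, tested up) differed in sign between median, mean or test. Of 16440 genes, edgeR called 0, with 1123 at an unadjusted p under 0.05 where 822 would be expected by chance. DESeq2 and limma-voom with quality weights called 0 too, with 1237 and 3525 at an unadjusted p under 0.05 for genes whose knockout effect differs between tissues. With edgeR 1 gene was called, Ifi27l2a, without KO_ON_717651. The genes with the smallest p were Bcl3, a regulator of the NF-kappaB pathway, at -2.17 (SE 0.42), the interferon-stimulated Ifi27l2a at -1.81 (SE 0.36), Cd300ld3 at -3.69 (SE 0.84), Btnl9 at 2.56 (SE 0.61) and Nudt13 at -0.46 (SE 0.11), with adjusted p from 0.623 to 0.725. All but Nudt13 were low in corpus callosum. Knockout and wild-type means there were 0.239 and 0.690 CPM for Bcl3 and 0.341 and 1.10 CPM for Ifi27l2a. They were 0.0251 and 0.285 CPM for Cd300ld3 and 0.613 and 0.416 CPM for Btnl9.

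Across the 14904 genes tested in both tissues other than Zdhhc9, the knockout log2 fold changes had a Pearson correlation of 0.218 (Spearman 0.177), and 54.4% had the same sign. Genes are not independent replicates. Without the optic nerve libraries whose numbers also occur in corpus callosum, the correlation of knockout effects between tissues was 0.111. Besides Zdhhc9, 1 gene, Apln, was called in both tissues.

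Between the tissues, 4743 of 16440 genes differed by a log2 fold change of at least 1, with 2340 higher in optic nerve and 2403 higher in corpus callosum. Among the largest differences, members of the fibroblast list were higher in optic nerve, namely the collagen gene Col3a1 at 6.97 (SE 0.23) and the small proteoglycan genes Ogn at 7.07 (SE 0.17) and Fmod at 9.08 (SE 0.31). Higher there too were the lubricin gene Prg4 at 8.11 (SE 0.25) and the retinoic acid enzyme gene Aldh1a2 at 7.60 (SE 0.34). So were the organic cation transporter gene Slc47a1 at 11.12 (SE 0.32), Wnt6 at 10.37 (SE 0.28), the growth hormone gene Gh at 12.85 (SE 1.23), Itih2 at 6.97 (SE 0.26) and the angiotensinogen gene Agt at 6.93 (SE 0.15). Genes that neurons express were higher in corpus callosum, such as the somatostatin gene Sst at -7.09 (SE 0.52), the vesicular glutamate transporter gene Slc17a7 at -6.38 (SE 0.98), the glutamate receptor gene Grin2b at -6.18 (SE 0.50), the dendritic gene Ddn at -7.35 (SE 0.37) and the calcium sensor gene Hpca at -6.14 (SE 0.43). Thbs4 at -7.91 (SE 0.29), Caln1 at -6.19 (SE 0.32), Fam163b at -6.16 (SE 0.61) and Wipf3 at -6.13 (SE 0.44) were also higher there. Elp6 at -6.86 (SE 1.54) was high in the 4 callosum libraries with 2-digit numbers alone. Gfap was higher in optic nerve by 3.26 (SE 0.12, adjusted p = 3.85e-15) and Aif1 by 1.43 (SE 0.14). Pdgfra (0.88), Mbp (0.64), Mobp (0.62), Mog (0.43) and Mag (0.27) were higher there by less than 1. Gpr17 (-0.63) and Zdhhc9 (-0.30) were lower, and Cnp (-0.09) and Myrf (0.06) did not pass.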

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

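The tests on cortical and striatal levels, the whole lineage, the change shared by both tissues and endothelial cells were chosen after the results were seen. So were those on the separate parts of the optic nerve lists and on gene counts without Zdhhc9. The others were written down before they were run. Among these, the tests on grey matter, on the neighbours of Apln and on KO_ON_719856 address patterns already seen in the results. Of 228 groups of library values, 14 held a library far from the rest of its group, where chance gives about 1 in 20 groups, or 11.4 here.

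Mature oligodendrocyte, myelin and cholesterol lists were lower by camera in knockout corpus callosum, while neuron markers were higher by the same test. More neighbouring grey matter in the knockout dissections would move these lists the same way, but with the neuron marker level as a covariate the mean level over the 3 lists still differed by -0.282 (SE 0.088, permutation p = 0.0152), against -0.446 (SE 0.125, p = 0.0130) without it. That level may not remove striatal markers in full. With cortical and striatal levels as covariates the difference was -0.277 (SE 0.151, permutation p = 0.0368, and 0.0996 for its ratio to the error), so grey matter cannot be told apart from a change in white matter. Striatal markers were higher in knockout by 0.853 (exact p = 0.0238, adjusted p = 0.0863), and with 2 covariates 11 libraries leave an error of this size. Fewer cells of the whole lineage would lower precursor markers as much. Yet the mature marker level minus the precursor level within libraries differed by -0.399 in knockout against wild type (SE 0.123, permutation p = 0.0152). Mature markers thus fell by more than precursor markers, although precursors also live in grey matter. A change with the knockout shared by both tracts may account for it, but the same mean level differed by -0.125 in optic nerve (SE 0.097, exact permutation p = 0.238), and with 5 against 4 libraries this cannot be told apart from no change. Of 100 groupings of the callosum libraries, 5 gave as many called lists as the real 19 (highest other 22), so chance is not excluded for the number of lists.

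Apln was lower in knockout libraries of both tissues and lies on the X chromosome near Zdhhc9. An effect on the whole region around the targeted locus would lower its neighbours. The other 14 tested genes within 1 Mb had a median of -0.0216 in corpus callosum (SE 0.10, taken over genes) and -0.0608 in optic nerve (SE 0.0575). A regional effect was set to need a median below -0.2, which neither tissue reached. The bound written down for setting it aside was a median above -0.1 by more than the error. Neither tissue met that bound, so a weaker effect on the region stays open. Fewer endothelial cells, which express apelin, would lower the endothelial and mural list, whose median was -0.0719 (SE 0.0507) in corpus callosum and -0.0119 (SE 0.0644) in optic nerve, far from the fall of Apln. A local effect on Apln alone, through an element in the targeted region or a linked variant of the parent strain, and a response to the loss of the enzyme both stay open and were not tested.

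Interferon, photoreceptor, neuron and immediate early lists were higher in knockout optic nerve. A single library, KO_ON_719856, holding retinal or inflammatory transcripts could be the source. Without it the median over all 56 members of the 4 lists was 0.330 (SE 0.042, taken over genes) against 0.435 with it. That fall was smaller than the one set for this explanation. But 34 of the 56 members belong to the neuron and immediate early lists, so the pooled median cannot decide for photoreceptor and interferon genes. Its error measures no spread between libraries either. The medians moved from 0.435 to 0.212 (SE 0.054) for the photoreceptor and interferon members and from 0.415 to 0.359 (SE 0.058) for the neuron and immediate early members, but these parts were set after the medians of each list were seen, so they do not decide whether that library is the source of either. Of 100 groupings, 67 gave as many called lists as the real 10 in optic nerve (highest other 17), so chance remains open for all of them.

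Groupings of the libraries, the real one among each 100, were compared for the remaining results. For genes in corpus callosum, 2 of 100 gave as many as the real 6, and the highest other gave 471; that many points to a structure of these samples. It put all 4 libraries with 2-digit numbers on the same side, but so did 7 others, of which 6 called 0 genes, so the number format by itself does not account for it. The count with the format as a covariate was 10 and in the longer format alone 2. Zdhhc9, the targeted gene, is bound to be called in the real grouping. Without it the real count is 5, and again 2 of 100 gave as many, fewer than the 5 in 100 set for chance. These 100 are a part of the 462 possible groupings, so that share is itself uncertain. It concerns the number of genes in corpus callosum and speaks for no single gene among the 5. For genes in optic nerve, 4 of 100 gave as many as the real 2, with a highest other of 16, but without Zdhhc9 the real count is 1, Apln, and 7 of 100 gave as many, so chance is not excluded for that count. For genes between tissues chance is excluded, where 1 of 100 reached 4743 and the highest other was 1249. For genes whose effect differs between tissues the real count is 0, which all 100 of 100 reach (highest other 5), so the groupings say nothing about it. Chance is not excluded for lists whose effect differs (13 of 100, real 16, highest other 21) or for the correlation of the effects (9 of 100, real 0.218, highest other 0.385).

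The knockout effect in corpus callosum minus that in optic nerve passed camera, though not with an estimated correlation, for 16 lists. The medians were -1.07 for interferon response, -0.857 for antigen presentation, -0.422 for myelin proteins, -0.198 for ribosomal proteins, -0.373 for mature and -0.350 for newly formed oligodendrocyte markers, -0.612 for reactive astrocytes, -0.394 for microglia, -0.533 for damage-associated microglia, 0.669 for striatal neurons, -0.215 for cholesterol synthesis, -0.175 for fatty acid and sphingolipid synthesis, -1.05 for photoreceptors, -0.160 for lineage transcription factors, -0.270 for immediate early genes and -0.852 for red blood cells.

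Single libraries far from their group were the following. Apln was 18.4 CPM in KO_CCg_717651 (others 23.7 to 27). Slco3a1 was 66.1 CPM in KO_CCg_693452 (others 52.3 to 57.4) and 72.1 CPM in WT_CCg_685232 (others 101 to 109). The neuron marker level was 6.13 mean log2 CPM in KO_CCg_29 (others 7.27 to 7.94). In KO_ON_719856 the 10 most abundant genes held 14.3% of counts (others 11.4 to 12), Mbp was 25562 CPM (others 33393 to 36071), the damage-associated microglia level was 6.74 (others 5.22 to 5.62) and the photoreceptor level 3.09 (others -0.31 to -0.02). The endothelial level was 5.44 in KO_ON_717651 (others 5.77 to 5.89). In wild-type optic nerve, mitochondrial transcripts held 3.34% of counts in WT_ON_719857 (others 4.22 to 4.39) and the red blood cell level there was 7.95 (others 6.10 to 6.22). Ppfia3 was 25.2 CPM (others 22.5 to 22.9) and Bcat1 92.4 CPM (others 61.2 to 62.0) in WT_ON_700858, and the ependymal level was 2.20 in WT_ON_717652 (others 0.98 to 1.03).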

How the results depend on the processing

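The pair of covariates (neuron level with number format, cortical with striatal levels), the set without KO_ON_719856 and WT_ON_701297, the lists in the longer number format, the replicate block with an added pair and the exact permutations of list levels were added after the data were seen; all other alternatives were planned. For named genes, 852 values with 1 library left out kept direction and side of the threshold, 34 lost their call, 2 gained one and 12 reversed; under the other settings 757 kept them, 24 lost and 31 gained a call and 12 reversed. For called lists the counts were 577 kept and 40 lost with 1 library left out, and 229 kept, 20 lost and 10 reversed otherwise. Where no cause is named below, the cause was not tested.

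For genes changed in corpus callosum, 6 became 11 at an adjusted p under 0.1, 167 with DESeq2, 2786 with limma-voom and quality weights, 41 in the joint fit, 10 with number format as a covariate, 2 in the longer format alone (fewer libraries) and 2 with cortical and striatal levels as covariates; with 1 library left out it ran from 2 to 41. For genes changed in optic nerve, 2 became 38 with DESeq2, 1 without the libraries whose numbers hold a letter and 1 without KO_ON_719856 and WT_ON_701297; with 1 library left out it stayed at 2 to 2. For genes whose knockout effect differs between tissues the range was 0 to 1. For genes that differ between tissues it was 4261 to 5603 over all alternatives and 4669 to 4845 with 1 library left out. For gene lists changed in corpus callosum, 19 became 0 with an estimated correlation, 7 with fry, 3 by exact permutation and 4 within formats (17 to 21 with 1 library left out). For gene lists changed in optic nerve, 10 became 0 by each of the estimated correlation, fry and permutation (9 to 13). For gene lists whose knockout effect differs between tissues, 16 became 0 with an estimated correlation and with fry (15 to 18). The correlation of knockout effects between tissues, 0.218, was 0.111 without the optic nerve libraries whose numbers recur in corpus callosum and 0.254 for genes with a log2 CPM of at least 3.

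Reversed values were small. With the neuron level as a covariate, list oligodendrocyte transcription factors in corpus callosum had a median of 0.0324, list neuron markers in corpus callosum -0.0293 and list cortical neuron markers in corpus callosum -0.154. With neuron level and number format these were 0.0224, -0.0395 and -0.174, list opc markers in corpus callosum was 0.0362 and Myrf in corpus callosum 0.0432. With cortical and striatal levels, the transcription factors were at 0.00112, cortical neurons at -0.0180 and list striatal neuron markers in corpus callosum at -0.00973; a marker list given its own level as a covariate must move to near 0. Mag in optic nerve was -0.000309 with DESeq2 size factors, -0.00119 with the stricter filter, -0.000488 with DESeq2, -0.00461 with limma-voom and -0.0331 without the libraries whose numbers hold a letter (-0.0554 to 0.0946 with 1 library left out). Cnp in optic nerve was -0.0296 with a surrogate variable and -0.0484 with the neuron level (-0.0856 to 0.138). Without KO_ON_719856 and WT_ON_701297, Aif1 in optic nerve was -0.101, Gpr17 in optic nerve 0.0557 and Gfap in optic nerve -0.0800; with 1 library left out they ran from -0.111 to 0.234, -0.186 to 0.0570 and -0.0616 to 0.115. Elp6 in the tissue comparison was 0.00933 with a fixed replicate block, which drops the 2-digit libraries that carry its high level.

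For genes that differ between tissues, replicate numbers that occur in both tissues were tried as a replicate block. The difference between tissues then held 4737 genes with a limma block and 4261 with a fixed block in edgeR, the effect that differs between tissues held 0 genes, and the consensus correlation was -0.112. Of the 4 pairs, correlations ran from -0.293 to 0.303, 1 was above 0.1 and 1 was highest with its own number, so they share a number, and a shared animal is not visible in the values. With the limma block, Elp6 in the tissue comparison lost its call (adjusted p = 0.0763). WT_CCg_7198587 and WT_ON_719857 have numbers that differ by 1 digit and may be a pair; their correlation was 0.0667, below the 0.0971 of WT_CCg_28 with the same nerve. Taken as a pair in the replicate block, they gave 4741 genes between tissues with limma and 4285 with a fixed block, and 0 genes whose effect differs (consensus correlation -0.0626).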

Other observations

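Hormone transcripts of the pituitary were present in several optic nerve libraries and nearly absent from corpus callosum, values picked out after they were seen. Gh, which codes for growth hormone, was at 79.8, 1663, 8.89, 2739 and 71.1 CPM in KO_ON_48038A7, KO_ON_48118A4, KO_ON_693452, KO_ON_717651 and KO_ON_719856. It was at 95.6, 36.2, 93.7 and 26.6 CPM in WT_ON_700858, WT_ON_701297, WT_ON_717652 and WT_ON_719857, against 0.350 CPM or less in corpus callosum. Prl, which codes for prolactin, was at 10.2, 148, 0.766, 386 and 6.40 CPM in the same knockout nerves and at 9.71, 4.02, 14.9 and 1.78 CPM in the wild-type ones. Pomc, the precursor of several pituitary peptides, reached 176 CPM in KO_ON_48118A4, against 1.95 to 23.1 CPM in wild type. The library WT_ON_717652 held 468 CPM of the granin gene Chga and 24.7 CPM of the transcription factor gene Pitx1. Skeletal muscle markers had a mean level of 1.11 log2 CPM in WT_ON_701297 and of -0.63 or less in the other 8 nerves.

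Corpus callosum libraries with 2-digit sample numbers differed from those with longer numbers in 4320 of 16228 genes by edgeR (2244 higher, 2076 lower), a comparison that the labels do not name and that was planned only as a covariate. Elp6, a subunit of the elongator complex, was at 3446 to 4421 CPM in the 4 libraries with 2-digit numbers and at 10.9 to 18.5 CPM in the 7 callosum libraries with 6 or 7 digits (10.1 to 17.6 CPM in the optic nerve ones), and Tulp1 was higher by 4.88 (SE 0.19). Of the 52 genes higher by a log2 fold change of at least 2, 36 are annotated as pseudogenes. Cell cycle genes had a median of 0.67 (camera adjusted p = 1.3e-05), lineage transcription factors 0.18 (0.0042) and myelin proteins 0.22 (0.0202), while neuron markers had -0.86 (3.5e-06), cortical neurons -1.04 (2.0e-04), fibroblasts -0.57 (0.0292) and oxidative phosphorylation -0.21 (2.9e-06); with an estimated correlation every one had an adjusted p of 0.838. Both genotypes have libraries of each format.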
